A study of Mus musculus with 27 samples.

How the data were processed

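The samples were sorted cells of adult mouse bone marrow. Per the labels, cells were depleted of erythroid, myeloid, T, NK and mature B cells and sorted as pro-B, large transitional (LTr) pre-B or large pre-B cells; the Chd4 series was of mixed C57BL/6 x 129/Sv background and the Ebf1 series of C57BL/6. The 13 RNA libraries were stranded mRNA libraries, the 12 ATAC libraries covered 4 groups of 3, and the 2 ChIP libraries, for Mi-2β and CTCF, came from WT large pre-B cells. The submitters' processing notes name bcl2fastq 1.8.3 and, without versions, STAR, Bowtie2, MACS2, HOMER and DESeq2, and the mm10 build, and do not say which tool served which file.

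The authors deposited 1 RNA table per series with a normalized signal per gene and library, headed as reads. The values were tested on the files: the libraries of each series summed to nearly the same total, and low values were whole multiples of 1 step per library, so that dividing by the step gave whole reads within 0.1 for 100% of values. The authors also deposited the log2 fold change of their DESeq2 comparison, positive where the mutant was higher. The authors deposited a p-value and an adjusted p-value of that comparison beside each log2 value. The ATAC file for LTr pre-B cells holds, per the file headers, the pileup signal at each summit. The same deposited file gives a fold enrichment, the ratio of treatment to control. It also gives deposited columns of -log10 p and -log10 q, whose headers were unreadable and were identified by their order and values. Per the region names, this was 1 MACS2 call with Chd4 null as treatment and WT as control, with the replicates not separated. The deposited list of regions common to pro-B and pre-B holds positions and annotation with no signal. The deposited ChIP files hold HOMER peak tables with a tag signal, a fold ratio to the control and to the surrounding region, a p-value and a peak score of the authors' own. Per the file headers, CTCF peaks were called against an input library at an FDR of 0.001 and a fold of 4, while the Mi-2β file has no such lines.

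There were 24052 gene rows for the Chd4 series and 24537 for the Ebf1 series, and 11 symbols occurred more than once in the Chd4 table. A share of 96.6% of the gene symbols of the Chd4 series was found in the reference annotation, and 98.3% of these lay on the same chromosome within 1000 bp, which was the check of the build. The recovered reads in genes were 10090168 and 18865332 in WT pro-B replicates 1 and 2, 22406588 and 26900268 in Chd4 null pro-B, 14818481 and 19346109 in WT LTr pre-B, and 12858741 and 27650051 in Chd4 null LTr pre-B. In the Ebf1 series they were 14180795 and 13038577 in the libraries labelled Ebf1 null and 8353602, 11566329 and 27109039 in WT, and the step of replicate 1 labelled Ebf1 null lay so near 1 that its reads are uncertain. A chi-square test between replicates gave 23.5 to 168 per gene, so replicates differed by more than read sampling. PCR copies cannot be told from separate molecules, so intervals cover counting error only. The depth of the ATAC libraries is unknown from the deposited files, and the CTCF header gives 30590960 tags.

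Expression was tested with limma 3.58.1 (R 4.3.3) with an intensity trend, on log2 of the value plus 1, for genes with a mean of at least 10 normalized reads. This left 13239 genes in the Chd4 series and 12134 in the Ebf1 series. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 4 groups of the Chd4 series shared 1 fit, with contrasts for Chd4 loss in each stage, for the difference between these effects (the interaction) and for the stage step in each genotype. The test planned before the data were examined was edgeR on counts, with limma in its place for normalized values, and the deposited values were normalized. The design gave the Ebf1 series no batch term; a term for replicate 1 against replicates 2 and 3 was added after the values were seen. A total of 27 gene lists were fixed before the data were examined and tested with camera of limma at a preset correlation of 0.01, for lists with at least 5 tested genes, with adjustment over lists; the estimated correlation and fry of limma were alternatives. The lists described for each comparison were chosen after their results were seen.

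Named genes followed a rule fixed before the data were examined. They are the targeted gene; the 6 genes with the largest log2 change in each direction among those called, with no overlap between the groups' libraries and a mean above the median, without antigen receptor segments, ribosomal pseudogenes and genes with provisional names; up to 4 members with the smallest adjusted p of each list described; and Ebf1 in the Chd4 comparisons and Chd4 in the Ebf1 comparison. For regions they are the 3 with the largest fold or score and the region with the smallest p of each named gene. Genes named for the interaction beyond this rule, Mpo and S100a8 as myeloid markers, and the sex-linked and housekeeping genes that separate replicates were chosen after their values were seen.

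Region overlaps were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 at a minimum of 1 bp, and checked with bedtools 2.31.1. The background was the mean of 100 shifts of all positions along their chromosomes. Regions of the pre-B list were assigned to the gene with the nearest start site in the RNA table, and those of the common list as deposited. Shares of genes with a region were compared by Fisher's exact test, two-sided, between risen and fallen genes, since the deposited lists hold no closed regions. Genes and regions are not independent replicates in these tests. Figures were drawn with matplotlib 3.10.9.

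The tests were run on simulated data with 100 changed genes at each fold. The changed genes were drawn from those above the median abundance, with the same dispersion for every gene. The recovery rates therefore do not cover genes of low abundance. In the Chd4 series limma recovered 87% (pro-B) and 90% (LTr pre-B) of 2-fold changes and 100% of 4-fold changes, with 1 and 0 false calls, at a simulated replicate SD of 0.153 on the log2 scale. In the Ebf1 series it recovered 1% of 2-fold and 78% of 4-fold changes without the batch term. With the term it recovered 100% of both, with 33 false calls among all unchanged genes. The simulated data held a random shift per gene in replicate 1, the split that the term fits, so this gain was built in. The difference of WT replicate 3 in sex-linked genes was not simulated. The simulated spread was set to the observed replicate spread after a wider first setting had recovered few changes, and the spread of the WT large pre-B libraries (0.39) was above the simulated 0.271. The region overlap code found 625 of 625 known overlaps and 0 wrong ones.

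The alternatives were quantile normalization, no filter on low values, pseudocounts of 0.1 and 5, a minimum absolute log2 change of 1, a fit of the compared groups alone, removal of antigen receptor segments, the replicate number as a block, each library left out in turn, other set tests, and other overlap, threshold and distance rules for regions. Added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of the Chd4 series, the Ebf1 batch term, replicates 2 and 3 of the Ebf1 series alone, stratification of genes by WT abundance and further threshold choices for regions. Count tests were not run on the Ebf1 series because the reads of 1 library are uncertain. A total of 6 columns of another sample set in the Ebf1 table matched no sample of the series and were not analysed here. ATAC values per replicate, closed regions and raw reads were not analysed here, since the processed files do not hold them.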

Results

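Gene expression, chromatin accessibility and factor binding were measured in B cell precursors of adult mouse bone marrow. The 13 RNA libraries came from pro-B cells (WT and Chd4 null, 2 libraries each), large transitional (LTr) pre-B cells, the stage that follows (WT and Chd4 null, 2 each), and large pre-B cells (3 WT and 2 labelled Ebf1 null). Chd4 encodes Mi-2β, the ATPase of the NuRD nucleosome remodelling and deacetylase complex, and Ebf1 is a transcription factor that specifies the B lineage. ATAC-seq, which marks open chromatin, covered the pro-B and LTr pre-B groups with 3 libraries each, and ChIP-seq of Mi-2β and of the architectural protein CTCF used 1 library each from WT large pre-B cells grown on stroma with IL-7. The reads assigned to genes ranged from 10090168 to 27650051 per library in the Chd4 series and from 8353602 to 27109039 in the Ebf1 series. Expression values are normalized reads per gene, given as mean ± SD with n = 2 per group unless stated, and log2 changes carry their SE. The labels do not say that replicates were separate animals, so p-values measure only the spread between these samples.

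Chd4 itself was lower in every library labelled Chd4 null than in every WT library of the same stage. In pro-B cells it stood at 20046 and 21866 in the WT libraries and at 11264 and 11053 in the null ones. In LTr pre-B cells it stood at 18450 and 19526 in WT and at 15531 and 13888 in null. The log2 change was -0.91 (SE 0.11, limma adjusted p = 0.00207) in pro-B and -0.37 (SE 0.11, limma adjusted p = 0.0423) in LTr pre-B cells, and the values do not separate exons, so they do not show how much intact transcript was left. The authors' deposited table gives log2 changes of -0.88 and -0.40. Chd4 lies on chromosome 6 from 125096163 to 125130501 of the mm10 build. Ebf1 went against its label: it stood at 13470 and 11343 in the libraries labelled Ebf1 null and at 4977, 7669 and 7329 in the WT libraries. The reads span the whole gene on chromosome 11 (44618100 to 45008096), so a deletion of some exons that leaves a transcript would not be seen.

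**Figure D1:**
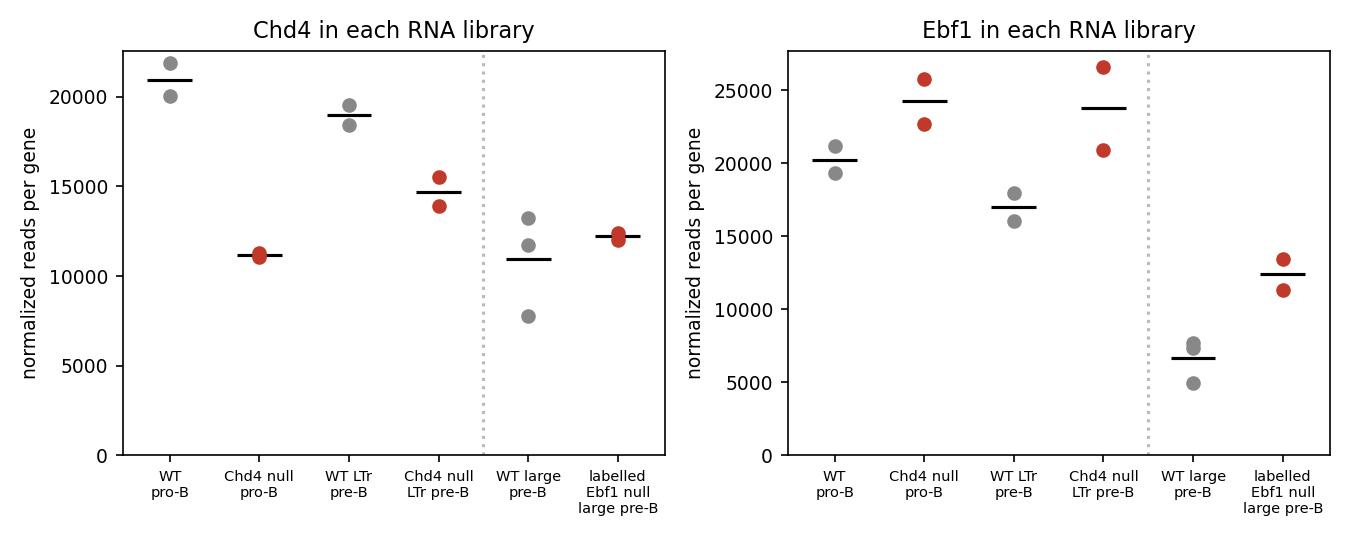
Normalized reads of Chd4 (left) and Ebf1 (right) in each of the 13 RNA libraries, with points for libraries (gray WT, red mutant by label) and lines for group means. The dotted line separates the 2 series, which were normalized apart, and Ebf1 is higher in both libraries labelled Ebf1 null than in the 3 WT large pre-B libraries.

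The first comparison asked what Chd4 loss did to expression in pro-B cells. Several genes rose from low levels: Lama5, a laminin chain of basement membranes, rose from 9.39 ± 2.90 to 1587 ± 69.7 reads, and Fgd5, an activator of the GTPase Cdc42, rose from 73.2 ± 3.20 to 4079 ± 245. Paralogs of Chd4 rose too, with Chd3 going from 5529 ± 335 to 12984 ± 564 and Chd5, best known from neurons, from 7.26 ± 7.04 to 195.4 ± 2.01. Among the genes that fell were Enpep, which encodes the BP-1 antigen of early B cells (2955 ± 328 to 387.4 ± 172), and Il2ra, the IL-2 receptor alpha chain (188.8 ± 56.7 to 25.8 ± 13.2). In all, 1608 genes rose and 1072 fell of 13239 tested.

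The genes with the largest increases also included Mdk, a growth factor (log2 5.58, SE 0.25), Smoc1 (5.44, SE 0.29), the receptor phosphatase Ptprf (5.43, SE 0.24) and the glutamate receptor subunit Gria2 (4.54, SE 0.20), which reached 9466 ± 1631 reads. Those with the largest decreases were Cacna2d1, a calcium channel subunit (-4.67, SE 0.61), Col5a3 (-3.01, SE 0.78), Enpep, Il2ra (-2.88, SE 0.36), Scn4b (-2.69, SE 0.23) and Cep164 (-2.62, SE 0.13). Of the 15 NuRD genes, 3 rose (Chd3, Chd5 and Gatad2a, log2 0.97, SE 0.08) and 3 fell, Chd4 among them; adjusted over the list alone 5 rose and 3 fell, and camera gave adjusted p = 0.618. Ebf1 did not pass (log2 0.26, SE 0.15, limma adjusted p = 0.274).

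Of 25 B lineage transcription factors, 8 rose and 3 fell (10 and 4 adjusted over the list alone). Mef2c rose by 1.07 (SE 0.11), Foxo1, which drives Rag gene expression, by 1.01 (SE 0.15) and Irf4, a factor of pre-B and plasma cells, by 0.93 (SE 0.14), while Id3, an inhibitor of E proteins, fell by 0.98 (SE 0.16). Camera gave adjusted p = 0.0413 for an increase of the list and 0.583 with an estimated correlation. Of 21 genes of the p53 response, 4 rose and 0 fell (6 and 0 adjusted over the list alone): Sesn2 (log2 1.85, SE 0.24), the kinase Plk2 (2.41, SE 0.36), Pmaip1, which encodes the death inducer Noxa (1.43, SE 0.26), and Phlda3 (1.10, SE 0.27). Of 16 apoptosis regulators, 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them Bmf (1.46, SE 0.18), Bcl2l11, which encodes Bim (0.73, SE 0.14), and Bid (0.66, SE 0.15). Both lists had camera adjusted p = 0.0304, and 0.377 with an estimated correlation. Plasma cell genes held 4 risen members of 10 (5 adjusted over the list alone), with Prdm1, the regulator Blimp1, at 2.14 (SE 0.27), Xbp1 at 0.98 (SE 0.14) and Slamf7 at 0.98 (SE 0.14), and had the same camera values. Of 27 adhesion and migration genes, 8 rose and 1 fell (8 and 3 adjusted over the list alone), including the chemokine receptor Ccr7 (2.07, SE 0.26), the sphingosine receptor S1pr1 (1.81, SE 0.22), the tetraspanin Cd9 (1.62, SE 0.17) and vinculin, Vcl (0.96, SE 0.11), with camera adjusted p = 0.139. Camera called 3 lists lower: G2 and M phase genes (0 of 22 passed, median log2 -0.35, adjusted p = 0.0304), genes of the G1 to S transition and DNA replication (2 of 27 fell, median -0.21, adjusted p = 0.0421) and ribosome biogenesis and MYC target genes (3 of 22 fell, median -0.27, adjusted p = 0.0304). No member of these lists rose, 0, 2 and 2 fell adjusted over the list alone, and adjusted p = 0.945 for each with an estimated correlation. Of 8 genes of other tissues (neuron and muscle) 3 rose and 1 fell (5 and 1 adjusted over the list alone), with camera adjusted p = 0.167.

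The authors' deposited table called 1575 genes higher and 883 lower in the null pro-B cells, and 2152 of these genes were among the limma calls. All 2680 genes moved the same way in replicate 1 and in replicate 2, which their selection on these libraries favours. The replicates differ in Xist (under 40 reads in replicate 1 of all 4 groups of the series and at least 16950 in replicate 2) and have 1 library per group, so no test within a replicate number is possible. Without 1 null library 1019 or 1026 genes passed and without WT replicate 1 1745 passed; with only these 4 libraries in the fit 1724 passed. With the replicate block 2381 rose and 2057 fell. Myeloid markers were present in the WT pro-B libraries, with S100a8 at 8448 and 3835 reads against 344.2 and 751.9 in the null ones. The myeloid list had 1 risen and 0 fallen genes of 25, with a median log2 change of -0.60, and -0.66 after quantile normalization. The stem, NK and erythroid medians were -0.89, -0.75 and -0.47, while the T cell and stroma medians were 0.66 and 0.31. Camera called none of these lists in pro-B cells.

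In LTr pre-B cells, Chd4 loss raised Lama5 and Fgd5 as in pro-B cells and lowered genes of the cell cycle. Lama5 rose from 2.38 ± 3.37 to 1620 ± 147 reads, Fgd5 from 14.0 ± 2.16 to 2766 ± 8.87 and Ly6a, the stem cell antigen Sca-1, from 22.6 ± 9.96 to 1462 ± 469. Il2ra, which encodes CD25 and marks pre-B cells, fell from 4597 ± 69.2 to 746.6 ± 130, and Ccna2, cyclin A2, fell from 18774 ± 981 to 8550.2 ± 2065. In all, 2239 genes rose and 1045 fell of 13239. After quantile normalization 1805 rose and 1769 fell, and the median gene moved from 0.02 to -0.12.

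Stum (log2 8.20, SE 0.49), Ptprf (6.29, SE 0.24) and Mdk (5.87, SE 0.25) were the other genes with the largest increases, and Ly6a belongs to a family of near-identical copies, so its value is uncertain. The decreases were led by Il2ra (-2.63, SE 0.36), the metalloprotease Adam19 (-2.29, SE 0.54), Trib2 (-1.89, SE 0.30), the B lineage antigen Ly6d (-1.82, SE 0.18), the adaptor Sla (-1.66, SE 0.21) and the myosin light chain Myl4 (-1.65, SE 0.19). Among NuRD genes Chd3 rose by 1.12 (SE 0.11), Chd5 by 4.20 (SE 0.63) and Gatad2a by 0.55 (SE 0.08), and 1 gene, Chd4, fell of 15, with the same counts adjusted over the list alone; the list median was 0.03, and -0.07 after quantile normalization. Ebf1 did not pass (0.48, SE 0.15, limma adjusted p = 0.0568), while the authors' deposited table gives an adjusted p of 0.03 for it.

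Of 22 genes of the G2 and M phases, 0 rose and 16 fell (22 fell adjusted over the list alone). Ccnb2 was at -0.85 (SE 0.18), Foxm1, the transcription factor of mitotic genes, at -1.14 (SE 0.25) and Cdk1 at -0.82 (SE 0.18). Of 27 genes of the G1 to S transition and DNA replication, 10 fell and 0 rose (21 and 1 adjusted over the list alone), among them cyclin D3, Ccnd3, which proliferating pre-B cells use (-0.77, SE 0.12), Pcna (-0.64, SE 0.14), the ribonucleotide reductase subunit Rrm2 and E2f8 (-1.15, SE 0.26). Camera gave adjusted p = 1.1e-08 and 2.86e-06 for these lists, and 0.684 for both with an estimated correlation. Of 22 interferon response genes, 8 rose and 0 fell (12 and 0 adjusted over the list alone), including Oas1a (2.33, SE 0.30), Ifi44 (4.24, SE 0.69), the tethering factor Bst2 (1.01, SE 0.14) and Ifit2 (0.81, SE 0.13); camera gave adjusted p = 1.7e-04 and 0.772 with an estimated correlation. Oas1a has close family copies and is uncertain. Markers of other cell types moved in this comparison too: 6 of 25 myeloid genes (median 0.63, and 0.35 after quantile normalization), 5 of 18 stem and progenitor genes (median 0.33, and -0.21 after quantile normalization) and 3 of 11 T cell genes (median 0.60 and 0.46) rose and none fell. Adjusted over the list alone 7, 5 and 5 rose and 0, 1 and 0 fell, with camera adjusted p = 0.566, 0.372 and 0.115. Null replicate 2 stood apart: the myeloid median was 0.06 within replicate 1 and 1.20 within replicate 2, the erythroid median -0.04 and 1.35 and the stem median 0.06 and 1.14. Mpo stood at 226.2 and 5090 reads in the null libraries and at 216.6 and 1763 in WT, Elane at 0 and 1307 against 42.1 and 446.3. Neither passed, and the 6 myeloid genes that did, such as Itgam (3744 and 3910 against 933.2 and 883.1), were higher in both null libraries than in both WT ones, as passing favours. Of 22 ribosome biogenesis and MYC target genes 3 fell and 0 rose (0 and 0 adjusted over the list alone), with camera adjusted p = 0.0407 and 0.998 with an estimated correlation.

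Of 21 p53 response genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Sesn1 at 0.70 (SE 0.09), the receptor Eda2r at 4.59 (SE 0.84) and Plk2 at 1.86 (SE 0.36), while Gtse1, a gene that peaks in G2, fell by 0.91 (SE 0.18). Of 27 adhesion and migration genes, 11 rose and 3 fell (12 and 4 adjusted over the list alone): the integrin Itgal rose by 2.17 (SE 0.13), Cd9 by 2.60 (SE 0.17), Vcl by 1.51 (SE 0.11) and Icam1 by 1.18 (SE 0.12). Camera adjusted p values were 0.114 and 0.209 for these lists. Of 12 small pre-B genes, 2 rose and 4 fell (3 and 6 adjusted over the list alone): Rag1, which cuts antigen receptor genes, rose from 45203 ± 2759 to 96340 ± 19898 reads and Sell, L-selectin, rose by 1.18 (SE 0.23), while Il2ra and the NF-kB inhibitor Nfkbia (-1.13, SE 0.19) fell, with camera adjusted p = 0.209.

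The authors' deposited table called 2170 genes higher and 1376 lower, and 2916 of them were among the limma calls. All 3284 limma calls moved the same way in each replicate, which their selection favours. Without WT replicate 1, null replicate 1 or WT replicate 2, 1543, 1757 or 2038 genes passed. With the replicate block 3098 rose and 1896 fell.

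The effects in the 2 stages overlapped. Of the genes that rose in pro-B cells 1254 also rose in LTr pre-B cells, against 272 for independent lists, and of those that fell 541 also fell, against 84.6; 13 and 22 genes moved in opposite directions. The log2 changes correlated across genes with Pearson r = 0.83 and Spearman rho = 0.71 over 13239 genes, which are not independent replicates.

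The interaction term asked which genes responded differently to Chd4 loss at the 2 stages. Some genes that WT cells lowered on the way to LTr pre-B were lowered less without Chd4: Dntt, the terminal transferase of pro-B cells, went from 56289 ± 5752 to 10831 ± 137 reads in WT and from 53387 ± 1255 to 40767 ± 533 in null cells. Emp1 went from 10780 ± 3646 to 1405 ± 3.40 in WT and from 12207 ± 702 to 6817 ± 868 in null. Some genes that WT cells raised rose less without Chd4, such as Cd38, a surface enzyme that hydrolyses NAD, from 653 ± 134 to 5372 ± 231 in WT and from 2399.5 ± 274 to 3981 ± 268 in null. Others did not: Il2ra and Jchain had stage changes of 4.63 and 1.74 in WT and 4.88 and 3.46 in null cells, and neither passed the interaction test. In all, 85 genes passed (60 with a more positive effect of Chd4 loss in LTr pre-B, 25 with a more negative one). All 60 had a negative and all 25 a positive stage change in WT, which the shared WT libraries favour by construction.

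The differences between the 2 Chd4 effects were largest for Grk3 (log2 2.68, SE 0.39), Emp1 (2.05, SE 0.31), the calcium pump Atp2b4 (2.01, SE 0.27), Afap1l1 (1.99, SE 0.19), Dntt (1.98, SE 0.16) and Parvb (1.94, SE 0.29), and in the other direction for the motor protein Myo1e (-2.57, SE 0.39), Cd38 (-2.32, SE 0.22), the peptidase Cpm (-2.22, SE 0.26), Cmah (-2.14, SE 0.23), the chromatin reader Brwd1 (-1.94, SE 0.16) and Pik3c2b (-1.84, SE 0.27). Of 12 small pre-B genes, Irf4 (-1.28, SE 0.19) and Spib (-1.55, SE 0.24) passed with a negative difference (3 adjusted over the list alone). Of 14 mature B cell genes none passed and 3 did adjusted over the list alone, with Cd22 at -1.75 (SE 0.38), Klf2 at -1.56 (SE 0.34) and Tnfrsf13c, the BAFF receptor, at -0.78 (SE 0.16). Of 18 stem and progenitor genes none passed and 4 did adjusted over the list alone, with Kit, the receptor of stem cell factor, at 2.20 (SE 0.64), Lmo2 at 1.79 (SE 0.36), Angpt1 at 1.36 (SE 0.33) and Hhex at 0.75 (SE 0.19). Camera adjusted p values for these lists were 0.00241, 4.8e-04 and 0.00205, and 0.588 for each with an estimated correlation. Camera also called the G2 and M phase list (median -0.56, adjusted p = 2.3e-08) and the G1 to S list (median -0.30, adjusted p = 1.9e-04) lower and the interferon list (median 1.36, adjusted p = 2.5e-05) higher, again at 0.588 with an estimated correlation. None of their genes passed, and 0, 0 and 1 did adjusted over the list alone. Marker lists of other cells moved with the stem list, whose median was 1.41, and 0.97 after quantile normalization. The myeloid and NK medians were 1.13 and 0.83 (0.71 and 0.67 after quantile normalization, camera adjusted p = 0.138 for each). The erythroid and T cell medians were 0.33 and 0.40 and the stroma median -0.21. Few or none of these calls held when any of the 8 libraries was left out. Such a fit has 1 library in a group and fewer libraries to estimate the spread, so this drop cannot show what each library contributes. With edgeR on recovered reads 58 genes passed and with DESeq2 587. With the replicate block, for a pairing that the labels do not state, 706 passed (544 positive and 162 negative), and 692 with the block in edgeR. With the block 9 of 26 named values passed that had not. Neither Chd4 (0.54, SE 0.15, limma adjusted p = 0.183) nor Ebf1 (0.22, SE 0.21, limma adjusted p = 0.824) passed.

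In WT cells, the step from pro-B to LTr pre-B raised genes of pre-B and mature B cells and lowered genes of progenitors. Il2ra rose from 188.8 ± 56.7 to 4597 ± 69.2 reads, the transcription factor Spib from 5309 ± 289 to 32956 ± 553 and Syk, the kinase that relays pre-BCR signals, from 17546 ± 542 to 46907 ± 1871. Kit fell from 4196 ± 961 to 510.3 ± 310 and Cish, an inhibitor of cytokine signals, from 761.9 ± 136 to 126.8 ± 9.68. In all, 724 genes rose and 1309 fell of 13239, and after quantile normalization 806 rose and 904 fell, with the median gene moved from -0.09 to 0.02.

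Il2ra (log2 4.63, SE 0.36), Adam19 (4.56, SE 0.54), the Ras activator Rasgrp1 (4.50, SE 0.40), Fcrla (4.50, SE 0.72), Col5a3 (4.47, SE 0.78) and the polymerase Polm (4.38, SE 0.32) had the largest increases. Stum (-4.10, SE 0.49), Tmem119 (-3.43, SE 0.53), Kit (-3.16, SE 0.45), Emp1 (-2.90, SE 0.22), Grk3 (-2.60, SE 0.28) and Cish (-2.57, SE 0.17) had the largest decreases. Of 12 small pre-B genes 8 rose and 0 fell (8 and 1 adjusted over the list alone), including Spib (2.63, SE 0.17), Irf4 (1.94, SE 0.14) and Nfkbia (1.83, SE 0.19). Of 14 mature B cell genes 9 rose and 0 fell (9 and 1 adjusted over the list alone), including Klf2 (3.58, SE 0.24), Fcrl1 (3.33, SE 0.38), Cd22 (2.81, SE 0.27) and Tnfrsf13c (1.27, SE 0.11). Both had camera adjusted p values of 3.05e-06 and 9.55e-07, and 0.578 for each with an estimated correlation.

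Of 25 B lineage transcription factors 8 rose and 6 fell (12 and 6 adjusted over the list alone), with Bach2 at 2.00 (SE 0.13) and the early factor Erg at -2.08 (SE 0.15). Of 21 pre-BCR genes 8 rose and 5 fell (9 and 6 adjusted over the list alone), with the kinase Blk at 2.61 (SE 0.14), Cd72 at 1.98 (SE 0.15) and Syk at 1.42 (SE 0.12). Camera adjusted p values were 0.0103 and 0.0108, and 0.692 and 0.758 with an estimated correlation. Of 18 stem and progenitor genes 7 fell and 0 rose (11 and 0 adjusted over the list alone), with Lmo2 at -1.74 (SE 0.25), Angpt1 at -1.47 (SE 0.23) and Hhex at -1.03 (SE 0.14). Of 22 interferon response genes 5 fell and 0 rose (12 and 0 adjusted over the list alone), with Oas1a at -1.57 (SE 0.30), Irf7 at -1.43 (SE 0.35), Bst2 at -0.97 (SE 0.14) and Ifit2 at -0.88 (SE 0.13). Their camera adjusted p values were 3.1e-04 and 0.00167, and 0.692 and 0.758 with an estimated correlation. Of 14 antigen presentation genes 6 rose and 0 fell (6 and 1 adjusted over the list alone) and of 10 plasma cell genes 5 rose and 0 fell (5 and 1), with camera adjusted p = 0.0108 and 0.00804, and 0.734 and 0.578 with an estimated correlation. Myeloid genes moved with these lists: 3 of 25 fell and 0 rose (camera adjusted p = 0.00492, and 0.758 with an estimated correlation), with Mpo at 4869 and 16112 reads in WT pro-B and 216.6 and 1763 in WT LTr pre-B libraries. Without WT LTr pre-B replicate 1 or 2, 700 or 1176 genes passed, and with only the 4 WT libraries 1223 passed. Chd4 (-0.14, SE 0.11, limma adjusted p = 0.442) and Ebf1 (-0.25, SE 0.15, limma adjusted p = 0.322) did not pass.

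In Chd4 null cells limma called few genes in the same step. Il2ra rose from 25.8 ± 13.2 to 746.6 ± 130 reads, Jchain, the joining chain of secreted antibodies, from 690.7 ± 153 to 7536 ± 172, and Klf2 from 171.6 ± 54.7 to 685.1 ± 131. In all 35 genes rose and 0 fell by limma, with 1610 genes at unadjusted p under 0.05; edgeR on recovered reads called 16 risen and 0 fallen and DESeq2 289 and 137. With the replicate block, which the labels do not state as a pairing, 239 rose and 56 fell, against 1215 and 2334 in WT. With the block in edgeR 283 rose and 107 fell. The largest increases were those of Il2ra (log2 4.88, SE 0.36), Jchain (3.46, SE 0.41), the Ikaros family factor Ikzf3 (2.96, SE 0.39), Polm (2.80, SE 0.32), Myl4 (2.62, SE 0.19) and Trib2 (2.50, SE 0.30).

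The 724 genes that rose in WT had a median log2 change of 1.03 in WT and 0.46 in null cells, and 34 of them passed in null. The 1309 that fell had medians of -1.20 and -0.27, and 1 of them passed. To avoid the bias of choosing genes on the libraries that are then measured, the 500 genes with the largest change were chosen in 1 WT replicate. Their median signed change in the other WT replicate was 1.99 or 2.29, and in the null replicates it was 1.06 and 0.41, or 0.87 and 0.38. In null cells 1 small pre-B gene, Il2ra, rose of 12 (7 adjusted over the list alone), with Spib at 1.09 (SE 0.17, limma adjusted p = 0.0712) and Irf4 at 0.66 (SE 0.14, limma adjusted p = 0.142). With the replicate block 8 of 23 named values passed that had not, Spib and Irf4 among them, and 9 did with the block in edgeR and 13 with DESeq2. Klf2 (2.02, SE 0.24) was the mature B cell gene that rose of 14 (7 adjusted over the list alone), and Blk (1.45, SE 0.14) the pre-BCR gene that rose of 21 (7 adjusted over the list alone). Of 22 G2 and M phase genes 0 passed and 10 fell adjusted over the list alone, with Plk1 at -0.96 (SE 0.21), Aurka at -0.89 (SE 0.20) and Cdk1 at -0.77 (SE 0.18). Camera gave adjusted p = 6.3e-08, 1.5e-07, 5e-06 and 6.3e-13 for these 4 lists, and 0.412, 0.412, 0.464 and 0.479 with an estimated correlation. It called 14 lists, 7 in each direction. Those called lower included the myeloid (median -0.65), erythroid (-1.14) and stem lists (-0.30), with adjusted p = 0.0329, 0.0329 and 0.0365. With an estimated correlation these were 0.776, 0.776 and 0.708, and none of their genes passed. Leaving out 1 null library in turn gave between 0 and 11 genes, and with only the 4 null libraries in the fit 0 passed, with 1707 at unadjusted p under 0.05. Chd4 (0.40, SE 0.11, limma adjusted p = 0.227) and Ebf1 (-0.04, SE 0.15, limma adjusted p = 0.959) did not pass.

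**Figure D2:**
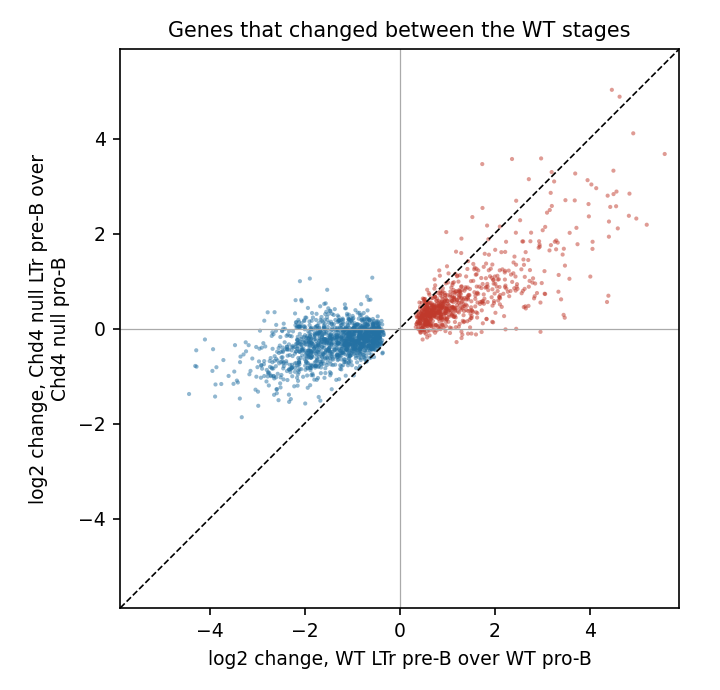
Log2 change from pro-B to LTr pre-B in Chd4 null cells (vertical) against WT cells (horizontal) for the 2033 genes that changed in WT, each a point (red rose, blue fell), with a dashed line of equal change. The median of the risen genes is 1.03 in WT and 0.46 in null cells, and that of the fallen genes -1.20 and -0.27.

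The Ebf1 series asked what Ebf1 loss did in large pre-B cells. In the libraries labelled Ebf1 null, genes of the interferon response and of progenitors were higher and genes of DNA replication and some MHC class II genes lower than in WT. Oasl2, an antiviral gene, stood at 612.8 ± 65.4 against 34.6 ± 7.06 reads (n = 2 and 3), Kit at 1252 ± 510 against 214.6 ± 99.5, and H2-Aa, a chain of MHC class II, at 585.7 ± 91.3 against 1654 ± 290. The replicate 1 libraries of both groups stood apart, with Gapdh, whose many pseudogene copies make its value uncertain, at 5.05 and 5.14 reads against 27.2 to 34.0 in the other 3. WT replicate 3 differed in sex-linked genes, with Xist at 18.0 and Ddx3y at 1308.5 reads, while Ddx3y was at most 1.24 in every other library of the series. The batch term does not account for that difference. Limma called 0 genes of 12134 with all 5 libraries and no batch term (1519 at unadjusted p under 0.05), and 601 risen and 94 fallen genes with a term for replicate 1 against replicates 2 and 3. All 695 moved the same way within each batch, which their selection on the same libraries favours. The authors' deposited table called 491 genes higher and 64 lower. Quantile normalization moved the median gene from 0.06 to -0.08. The values that follow are from the fit with the batch term, a fit chosen after the values were seen, and directions rest on labels that Ebf1 itself goes against. Ebf1 was at log2 0.96 (SE 0.21, limma adjusted p = 0.0491) with the batch term and 0.92 (SE 0.27, limma adjusted p = 0.25) without it, and Chd4 at 0.26 (SE 0.19, limma adjusted p = 0.406).

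The largest increases were those of Als2cl (log2 3.39, SE 0.33), Emb (3.29, SE 0.38), Gimap4 (3.23, SE 0.18), the interferon-induced GTPase Gbp7 (3.02, SE 0.34), Atp2b4 and Slfn2 (2.94, SE 0.45). The largest decreases were those of Nrgn (-2.42, SE 0.48), Tmprss3 (-1.72, SE 0.36), Fcrla (-1.52, SE 0.33), H2-Aa (-1.50, SE 0.22), Thop1 (-1.40, SE 0.26) and the kinase Sik1 (-1.22, SE 0.24). Of 22 interferon response genes 15 rose and 0 fell (21 and 0 adjusted over the list alone), including Oasl2 (4.13, SE 0.30), Oas3 (2.86, SE 0.39) and the RNA sensors Ifih1 (2.11, SE 0.31) and Ddx58 (1.61, SE 0.18). The list median was 1.63 within replicate 1 and 3.23 within replicates 2 and 3. Camera gave adjusted p = 2.4e-13 and 0.605 with an estimated correlation; without the batch term 0 members passed and 19 rose adjusted over the list alone, with Irf7 at 3.03 (SE 0.50).

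Of 14 stem and progenitor genes 4 rose and 0 fell (5 and 0 adjusted over the list alone): Ly6a (4.86, SE 0.48), Kit (2.65, SE 0.45), Lmo2 (1.19, SE 0.20) and Hhex (0.95, SE 0.21). Of 26 adhesion and migration genes 7 rose and 0 fell (10 and 2 adjusted over the list alone), with S1pr1 at 2.26 (SE 0.27), Itgal at 1.92 (SE 0.23), Icam1 at 1.53 (SE 0.22) and Sell at 1.10 (SE 0.17). Of 27 genes of the G1 to S transition and DNA replication 7 fell and 0 rose (20 and 0 adjusted over the list alone), with Rrm2 at -0.80 (SE 0.15), Mcm2 at -0.68 (SE 0.14), Mcm5 at -0.69 (SE 0.15) and the licensing factor Cdt1 at -0.82 (SE 0.18). Of 22 G2 and M phase genes 1 fell and 0 rose (21 and 0 adjusted over the list alone), with camera adjusted p = 1.5e-13 and 0.605 with an estimated correlation. Camera adjusted p values of the stem, adhesion and G1 to S lists were 0.00126, 0.01 and 2.4e-13, and 0.671, 0.605 and 0.605 with an estimated correlation. Of 13 antigen presentation genes 2 rose and 4 fell (5 and 4 adjusted over the list alone): H2-Aa, H2-Eb1 (-2.02, SE 0.36), H2-Ab1 (-1.17, SE 0.23) and Ciita, the activator of MHC class II genes (-1.50, SE 0.18), with camera adjusted p = 0.432. Without the batch term the median of that list was 0.07, and -0.11 after quantile normalization. Of 7 NK and innate lymphoid genes 3 rose and 0 fell (4 and 0 adjusted over the list alone): Il18rap (2.68, SE 0.44), Nkg7 (2.84, SE 0.54) and Klrb1c (2.16, SE 0.47), with camera adjusted p = 0.01 and 0.671 with an estimated correlation. The stem and NK medians were 1.35 and 3.27 within replicate 1 and 0.68 and 1.22 within replicates 2 and 3. Marker lists of other cells moved in the same way, with myeloid medians of 3.72 and 0.32 and erythroid medians of 3.65 and 0.62. Of 22 myeloid genes 2 rose and of 15 erythroid genes 0 rose (3 and 7 adjusted over the list alone), and none fell. Camera gave adjusted p = 4.97e-04 and 0.00593, and 0.671 for each with an estimated correlation. Beside these lists, Mpo stood at 1863 reads in replicate 1 of the libraries labelled Ebf1 null and at 16.5 in replicate 2, and between 23.8 and 30.95 in the WT libraries.

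Chd4-dependent genes were compared with those of the Ebf1 series. Of the genes that rose in Chd4 null LTr pre-B cells and were tested in both series, 375 also rose in the libraries labelled Ebf1 null, against 89.9 for independent lists (Fisher's exact test, odds ratio 11.8, adjusted p = 4.8e-167 over 20 such tests). Of the 94 genes that fell in the Ebf1 series 56 also fell in Chd4 null LTr pre-B cells, against 8.17 (odds ratio 16.3), and 6 and 0 genes moved in opposite directions. In pro-B cells 143 genes rose in both, against 62.8 (odds ratio 2.89), and 13 fell in both, against 8.34 (Fisher's exact test, odds ratio 1.66, adjusted p = 0.124). Without the batch term 0 genes were shared, since the Ebf1 set then held none. The log2 changes of the Chd4 null LTr pre-B and the Ebf1 comparison correlated with Pearson r = 0.53 and Spearman rho = 0.53 across 12013 genes, which are not independent replicates.

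Accessible chromatin was compared through 2 lists of regions. The LTr pre-B list held 41947 regions, which per their names come from 1 MACS2 call with Chd4 null as treatment and WT as control, so it lists regions more open in Chd4 null cells and holds no closed ones. Their median fold was 3.20, a value of the authors' own call without replicates. The list common to pro-B and pre-B held 24295 regions with positions and annotation alone, all of them within the pre-B list. Of these, 46.6% were intergenic, 41.4% lay in introns and 5.70% at promoters, and 20.6% carried LTR repeats, ERVK elements (11.2%) the most frequent family among them. Of the pre-B regions, 31.9% lay within 10 kb of a transcription start site. The regions with the largest fold were chromosome 4, 8965522 to 8966042 (18.8-fold), 275 kb from the start of Chd7, the nearest gene; chromosome 3, 153348769 to 153349642 (18.0-fold); and chromosome 2, 180522793 to 180523293 (17.9-fold), 23.1 kb from the start of Ntsr1.

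Genes that rose without Chd4 had such regions near them. The list assigned 22 regions to Ptprf, 11 to Stum, 9 to Fgd5 and 9 to Lama5, and 1 to Il2ra, 1 to Adam19 and 0 to Ly6d and Cacna2d1; Cep164, which fell, had 14. The most significant region of Fgd5 lay at chromosome 6, 92014904 to 92015462, 28.1 kb from its start (11.9-fold), and that of Ptprf at chromosome 4, 118276041 to 118276918, 14.9 kb from its start (11.2-fold). In pro-B cells 49.4% of the risen genes had a region of the common list within 10 kb, against 16.1% of the fallen genes and 19.2% of those that did not pass (risen against fallen, odds ratio 5.08, Fisher p = 1.8e-73). In LTr pre-B cells, with the LTr pre-B list, the shares were 63.3%, 30.2% and 32.7% (odds ratio 3.98, Fisher p = 4e-71). With every assigned region the odds ratios were 3.48 and 3.69. With regions within 10 kb and genes compared within quartiles of WT abundance they were 3.72 and 2.68, against 5.08 and 3.98 without quartiles. With 1 region per gene, that of the smallest p, within 10 kb, the odds ratio in LTr pre-B was 2.55. The share of genes that rose in LTr pre-B cells was 8.25% among the 6049 genes with no region within 50 kb of the start, 14.9% with 1, 23.8% with 2 or 3 and 40.2% among the 1795 genes with 4 or more. Fallen genes against those that did not pass gave odds ratios of 0.943 (Fisher p = 0.378) in pro-B and 0.93 (Fisher p = 0.268) in LTr pre-B with any assigned region, and 0.812 (Fisher p = 0.0156) and 0.89 (Fisher p = 0.103) within 10 kb.

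**Figure D3:**
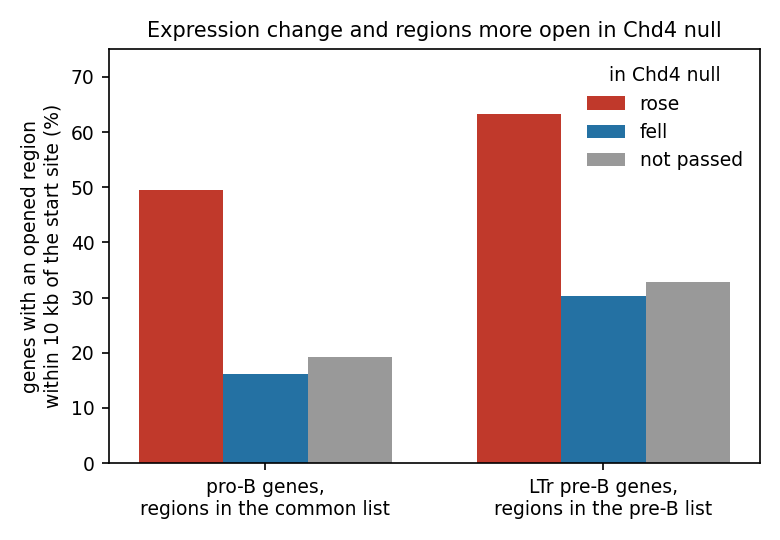
Percent of tested genes with a region more open in Chd4 null cells within 10 kb of the start site, by the expression change in Chd4 null cells (red rose, blue fell, gray not passed). The bars of the risen genes stand at 49.4% in pro-B and 63.3% in LTr pre-B cells and those of the fallen genes at 16.1% and 30.2%.

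Mi-2β binding in WT large pre-B cells was set beside CTCF binding and the opened regions, with 1 library per factor and therefore no replicate check. Of 20653 Mi-2β peaks, 41.1% lay within 1 kb of a start site, against 9.44% of 70248 CTCF peaks. CTCF peaks overlapped 32.2% of the Mi-2β peaks (95% Clopper-Pearson interval 31.5% to 32.8%, counting error only), and 1.41% after shifts of position, a 22.9-fold excess. The shifts did not keep peaks in open chromatin, so an excess over them cannot show binding beyond accessible sites that the lists share. This applies to each shifted share in this paragraph. Many Mi-2β peaks were weak, with a median of 6.85 tags against a lowest value of 5.24. Mi-2β peaks with the highest deposited scores lay at chromosome 8, 15519901 to 15520049; chromosome 16, 11144049 to 11144197, 9.59 kb from the start of Txndc11; and chromosome 11, 109011774 to 109011922. Of the Mi-2β peaks, 7.84% (7.48% to 8.22%) lay at a region more open in Chd4 null LTr pre-B cells, 13.1 times the 0.598% after shifts; CTCF peaks did so in 8.27% (8.06% to 8.47%), 9.82 times their shifted share. Of the pre-B regions that also stood in the common list 1.87% held a Mi-2β peak, against 7.16% of the others (odds ratio 0.247, Fisher p = 2.7e-159). Gria2, which rose in pro-B cells, had a region with a Mi-2β peak at its start site (chromosome 3, 80802595 to 80803014). The single regions assigned to Col5a3, which fell in pro-B, and Adam19, which fell in LTr pre-B cells, held one too. No region assigned to Lama5, Fgd5, Mdk or Ptprf held one. The cells also differed between the assays, since binding was measured after culture on stroma and accessibility in sorted cells.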

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

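The tests of depth, of the mixed sort with the replicate block, of other cell types, of the batch, of myeloid and erythroid cells and of a wrong label were chosen only after the results were seen, while the bounds for the mixed sort without the block and for opened chromatin were written before.

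The effect of Chd4 loss differed between the stages for 85 genes by the interaction test of limma. The log2 difference, LTr pre-B minus pro-B, was 2.68 for Grk3, 2.05 for Emp1, 2.01 for Atp2b4, 1.99 for Afap1l1, 1.98 for Dntt, 1.94 for Parvb, 1.86 for Erg, 1.76 for Fgd5, 1.61 for Cish and 1.58 for Cep164. It was -1.28 for Irf4, -1.55 for Spib, -1.84 for Pik3c2b, -1.94 for Brwd1, -2.14 for Cmah, -2.22 for Cpm, -2.32 for Cd38 and -2.57 for Myo1e. The adjusted p values of these 18 genes lay between 0.0292 and 0.0468.

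Fewer genes changed between the stages in Chd4 null than in WT cells. Lower depth of the null libraries is argued against by their reads, 22406588 and 26900268 in pro-B and 12858741 and 27650051 in LTr pre-B cells. WT libraries held 10090168 and 18865332, and 14818481 and 19346109, so null LTr pre-B replicate 1 went the other way. A larger spread is argued against in pro-B cells, with a median replicate SD (log2) of 0.136 in null and 0.195 in WT. In LTr pre-B cells it was close, 0.146 and 0.133. For 500 genes chosen in 1 WT replicate, the median null change was at most 53.5% of that in the other WT replicate. No genes were chosen in a null replicate, so that figure does not bear on depth or spread. A sort in which 1 fixed share of the null LTr pre-B cells was still at the pro-B stage stays open: with 33.1% of the cells past that stage, 4.67% of the 2033 genes lay over 3 SE from the predicted change, under the 5% bound, but 9.15% did with the SE of the fit with the replicate block. That share would have to differ between the null replicates. The median change was 53.5% and 37.9% of that in WT in replicate 1 and 20.5% and 16.6% in replicate 2. Null LTr pre-B replicate 2 correlated with null pro-B replicate 2 at Spearman rho = 0.992. For replicate 1 of the same groups rho was 0.982. Mpo stood at 226.2 and 5090 reads in null LTr pre-B and 4604 and 7556 in null pro-B cells. As a myeloid marker Mpo could also come from other cells, so it does not measure that share. A changed start and a partial change within each cell stay open too: of the 724 genes that rose in WT 218 were higher and 71 lower in null pro-B cells, of the 1309 that fell 338 and 180, by a comparison that uses the same WT pro-B libraries, and Cd38, Brwd1, Cmah, Pik3c2b and Myo1e rose in null pro-B cells and did not pass in LTr pre-B.

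Genes near silent in WT cells (a mean under 10 reads) made up 14.5% of the genes that rose in Chd4 null pro-B and 16.7% of those that rose in LTr pre-B cells. Genes were tested only at a mean of at least 10 reads over all libraries. Near-silent genes thus entered through other libraries, the null ones among them, so the filter favoured their rise. Under the same filter, genes with a null mean under 10 made up 3.08% and 0.957% of those that fell. RNA of other marrow cells stays open, although such cells were depleted before the sort: the highest median log2 change of 5 lists of other cell types was 0.66, which met the bound of under 1 set for excluding them, but that bound was wrong, since these genes were chosen for having risen and markers with a high WT level, such as Mpo in pro-B cells (4869 and 16112 reads), would hide a small share. In LTr pre-B cells 6 of 25 myeloid genes rose and 0 fell, each of the 6 in both null libraries, while the list median was 0.06 within replicate 1 and 1.20 within replicate 2. Opened chromatin near these genes is a candidate explanation: they had an opened region within 10 kb more often than near-silent genes that did not pass, with a lower odds ratio of 3.58 over the 2 stages. The near-silent genes that did not pass could enter the test through other libraries, such as those of the other stage. They are therefore not matched controls. The regions come from the same genotype, so which change came first was not tested.

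Interferon and progenitor genes were higher in the libraries labelled Ebf1 null, in which Ebf1 was not lower. A batch between replicate 1 and the others is argued against as the whole cause for the interferon genes, since their median was 1.63 or more within each batch. The progenitor medians were 1.35 within replicate 1 and 0.68 within replicates 2 and 3, the latter between the bounds set for either outcome. A difference between the batches alone would not raise genes within each batch, and 14 and 12 of these 14 genes were higher there. The genes are not independent, however, and each batch holds only 1 library labelled Ebf1 null. By the bounds set, a batch as the cause for the progenitor genes therefore stays undecided. Myeloid and erythroid cells in replicate 1 may be the source of the genes of those lists there, although such cells were depleted before the sort: within replicates 2 and 3 the higher of their medians was 0.62, between the bounds set for either outcome. The medians of these 2 lists within replicate 1 were 3.72 and 3.65. Whether such cells also gave progenitor genes there was not tested. Ebf1 reads were 1.86 times the WT mean, which a wrong label on both libraries would give and a deletion that leaves a transcript would give too, so these cannot be told apart from reads over the whole gene. The biological effect of Ebf1 loss therefore stays untested.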

How the results depend on the processing

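Tests of edgeR, DESeq2, the batch term, replicates 2 and 3 alone, the sharing of genes with the batch term and the stronger Mi-2β peaks against all CTCF peaks were chosen after the data were seen. Genes changed by Chd4 loss numbered 2680 in pro-B and 3284 in LTr pre-B cells, and both counts stayed within 1.5 times under quantile normalization, no filter, other pseudocounts, removal of receptor segments, edgeR and DESeq2. With an absolute log2 change of at least 1 they were 1437 and 1843, and 1176 for the WT stage step, by construction. With the compared groups alone, fewer libraries estimate the spread, and 1724 genes passed in pro-B, 1223 in the WT stage step and 0 in the null stage step. The interaction held 55 genes after quantile normalization, 41 without a filter and 587 with DESeq2. The null stage step held 75, 17 and 426 under the same settings and 16 with edgeR. The cause was not tested.

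The labels give the same replicate numbers to several groups but state no pairing, and only 2 numbers are shared. With the replicate block 4438 genes passed for Chd4 loss in pro-B, 4994 in LTr pre-B and 706 for the interaction. For the stage steps 3549 passed in WT and 295 in null cells. With the block in edgeR on recovered reads the counts were, in the same order, 4584, 5700, 692, 3752 and 390. In the Ebf1 series 1363 passed with the block, of 12151 tested genes, while the fit of all its libraries tested 12134. The fit without the WT library whose number no mutant library shares also tested 12151. That library was thus apparently left out of the block fit, so 1363 cannot be put down to the block alone. Deviations of libraries with the same number correlated by 0.42 to 0.68 across genes in the Chd4 series. In each group of that series Xist was at most 38.9 reads in replicate 1 and at least 16950 in replicate 2. The numbers thus mark a measured difference between libraries, which the fit without the block leaves in the spread.

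The Ebf1 comparison held 0 genes, 1 after quantile normalization, 3 with a pseudocount of 5, 695 with the batch term and 691 with replicates 2 and 3 only. The shared genes of the Chd4 and Ebf1 series, same direction, numbered 0 without the batch term and 156 (pro-B) and 431 (LTr pre-B) with it, or 89 and 282 at an absolute log2 change of at least 1. The cause was not tested.

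With 1 library left out in turn the counts ranged from 1019 to 2285 for Chd4 loss in pro-B, 1543 to 2348 in LTr pre-B, 0 to 4 for the interaction, 700 to 1451 for the WT and 0 to 11 for the null stage step, and 0 to 6 in the Ebf1 series. A lone library was taken to vary like the other groups.

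Gene list calls by camera numbered 7, 5, 6, 9, 14 and 11 over the 6 comparisons, and 0 in each with camera at an estimated correlation. With fry they were 5 for Chd4 loss in pro-B, 8 in LTr pre-B and 0 for the interaction. For the stage steps they were 12 in WT and 4 in null cells, and 5 in the Ebf1 series without the batch term. With the batch term the lowest fry adjusted p in that series was 0.0974, so fry called no list. The lists called differed between the tests. In LTr pre-B cells fry gave adjusted p = 0.0693 for the G2 and M phase list and 0.065 for both the G1 to S and interferon lists. It gave 0.392 for the ribosome list. Of the lists that camera called there, fry called only that of plasmacytoid and dendritic cells (adjusted p = 0.00917). Mi-2β peaks with a CTCF peak made up 32.2%, and 28.7% at an overlap of 50% of the shorter peak, 21.9% with the stronger 50% of each list and 33.6% with the stronger 50% of Mi-2β peaks and all CTCF peaks. Mi-2β peaks at regions more open in Chd4 null cells made up 7.84%, and 5.39% at an overlap of 50% and 7.03% with the stronger 50% of Mi-2β peaks. The cause was not tested. Over the named genes 2551 values kept their side of the threshold, 161 came to pass it and 251 no longer passed it. None that passed in either fit turned direction, and values that passed in neither were not checked for direction.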

Other observations

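The list of imprinted genes was written, and the comparisons below were chosen, only after values of these genes had been seen. Many imprinted genes, which are expressed from 1 parental copy, were higher without Chd4. Of 25 such genes 20 were tested, of which 13 rose and 0 fell in pro-B and 9 rose and 0 fell in LTr pre-B cells by limma. Over all 13239 tested genes 1608 rose in pro-B and 2239 in LTr pre-B cells. Genes were tested only at a mean of at least 10 reads over all libraries. Meg3, Rian, Mirg, Dlk1, H19 and Plagl1 had WT means under 10 and entered through the null libraries, so the filter favoured their rise. Meg3, a noncoding RNA of the Dlk1 cluster, stood at 401 ± 75.5 reads in null pro-B and 399 ± 49.3 in null LTr pre-B cells (SD, n = 2 each), against at most 2.29 in any WT library. Its neighbours Rian and Dlk1 had log2 changes of 7.42 and 4.66 in pro-B cells, and Rian one of 7.17 in LTr pre-B cells, where Dlk1 stood at 82.8 ± 25.7 reads. H19 stood at 339 ± 45.7 and 102 ± 63.3 reads against at most 4.58 in WT. Peg10 (log2 2.94 and 2.82) and its neighbour Sgce (2.05 and 2.75), Nnat (3.66 and 2.67) and the cell cycle inhibitor Cdkn1c (1.48 and 1.65) were higher too, while Mest, Impact, Peg13 and Zrsr1 had log2 changes between -0.09 and 0.44. In pro-B cells Airn was at -2.15 (limma adjusted p = 0.107) and Grb10 at -0.97 (limma adjusted p = 0.0558).

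Genes of plasmacytoid and dendritic cells were also higher in Chd4 null LTr pre-B cells, with 5 risen and 1 fallen of 11 (6 and 1 adjusted over the list alone). Camera of limma gave adjusted p = 0.0407 for this list and adjusted p = 0.684 with an estimated correlation. The median log2 change was 1.01, and 0.36 after quantile normalization. In pro-B cells 5 of these genes rose and 1 fell too (5 and 1 adjusted over the list alone), with a median of 0.49, and 0.25 after quantile normalization, and camera gave adjusted p = 0.0851.

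The libraries labelled Ebf1 null were set beside the normal stage step. Of 1213 genes that fell from WT pro-B to WT LTr pre-B and were tested in both series, 304 rose in the libraries labelled Ebf1 null with the batch term and 1 fell, with a median log2 change of 0.91, and 90.3% were higher. Of 706 genes that rose in that step 15 rose and 37 fell, with a median of -0.11. Over all 12134 genes of the Ebf1 series 601 rose and 94 fell. Markers of other cells moved in both comparisons. The myeloid and erythroid medians were -2.25 and -1.42 in the WT stage step. In the Ebf1 series they were 3.72 and 3.65 within replicate 1 and 0.32 and 0.62 within replicates 2 and 3. The log2 changes correlated across 12013 genes with Pearson r = -0.51 and Spearman rho = -0.34, and genes are not independent replicates. Dntt stood at 50106 ± 26967 reads in the libraries labelled Ebf1 null (n = 2) and 9923 ± 5204 in WT (n = 3).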
